A study of Mus musculus with 6 samples.

How the data were processed

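Gene expression was measured in total RNA of mouse brain with a 1-colour Affymetrix whole-transcript array read at the level of exon probe sets, on 6 arrays. Per the labels, 3 arrays came from control mice of the genotype APPPS1-FVB and 3 from mice of the genotype APPPS1-FVBxABCC1, called the knockout here after the sample titles. The labels give no sex, age or batch, and nothing says that the arrays are separate animals, so p-values measure only the spread between these samples.

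The table holds log2 signals with 2 decimals as deposited by the authors, and the submitters' processing notes name MAS5, with no version. The scale was read from the values themselves, which run from 1.69 to 14.41, and how the arrays were brought to a common scale is not given in the sources used here. Signals were taken without further normalization, because the medians of the tested probe sets lay between 7.04 and 7.09, a range of 0.05 that is under the limit of 0.1 set for quantile normalization. Pairs of arrays correlated between 0.984 and 0.990 over the tested probe sets, and no pair was identical.

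The part of the table analysed here holds 65535 probe sets. Of these, 6616 with IDs below the first named probe set were taken as control features of the array, from knowledge of how its IDs are ordered and not from a label, and were left out of the tests. Of the 58919 tested, 53644 had 1 gene symbol, 877 had several and 4398 had none in the platform's annotation, and no gene was named from a probe set with several. Of 5032 symbols, 4321 were current in the RefSeq gene table of GRCm38.p6, 698 were updated through a synonym and 13 were kept as given, which left 5017 genes with a median of 8 probe sets each. The build behind the array is not given in the sources used here, so the gene table served only for symbols, chromosomes, gene spans and the order of neighbours, and no coordinates are given. These genes lie almost all on 5 chromosomes: 4918 of 5017 are on chromosomes 1, 10, 11, 12 and 13. *Abcc1*, *App*, *Thy1*, *Trem2*, *Apoe* and *Ttr* had 0 probe sets among those tested and were not analysed here, so the targeted gene could not serve to check the labels. The 3 symbols placed on the chromosome of *Abcc1*, number 16, belong to probe sets whose ID neighbours lie on chromosomes 10 and 12, so the planned test of genes near *Abcc1* was not run.

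Knockout minus control was fitted per probe set with limma 3.58.1 (lmFit and eBayes without trend, R 4.3.3), two-sided, with Benjamini-Hochberg adjustment over all tested probe sets and a threshold of 0.05. A gene was represented by its probe set with the highest mean signal over the 6 arrays. The number of arrays limits the precision: an exact permutation test of 3 against 3 cannot give a two-sided p below 0.1. On simulated data with 58919 probe sets and 3 arrays against 3, the fit called 6 of 67 probe sets changed 1.5-fold, 27 of 67 changed 2-fold and 57 of 66 changed 4-fold, with 2 false calls in all. The simulated noise was normal and independent between probe sets, with each probe set's observed residual SD taken as the true one. These rates hold for that setting and need not hold for the real arrays.

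Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 42 of 46 lists that had a measured member. Camera with an estimated correlation and fry, which tests whether a list's genes move one way on balance, stood beside it. The lists, the tests and the rule for named genes were fixed before the data were examined. The rule took *Abcc1*, *App* and *Thy1*, up to 10 genes in each direction past the threshold, filled up to 8 per direction by the smallest raw p where too few passed, and 2 members with the smallest raw p from each of 6 lists. These 6 lists were amyloid processing, amyloid clearance, ABC transporters, plaque-associated microglia, choroid plexus and glutathione with oxidative stress. In that order they were fixed with 21, 25, 40, 27, 28 and 36 genes, of which 6, 2, 9, 10, 5 and 9 were measured. The rule also took 3 members of any other list past the threshold, and *Trem2*, *Gfap*, *Apoe* and *Ttr*. A further item of the rule is not reported here.

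The alternatives covered normalization, a filter that left out 1 in 3 probe sets, those of the lowest mean signal, the variance model, array weights, the replicate number as a block, each array left out, the mean of all probe sets of a gene, the set test and the threshold. Added after seeing the data were gene means and brightest probe sets tested per gene, control features included, lists with at least 3 measured members, gene means with fry or an estimated correlation, the fit without the genes of 2 runs of neighbours, and removal of a trend on gene span. The scan for runs of neighbouring genes was also added after seeing the data. It counted probe sets with a log2 difference of at least 1 in size and a raw p below 0.01 in windows of 50 neighbouring genes, against 10000 random orders of the genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.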

Results

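Total RNA of 6 mouse brain samples was profiled on exon-level whole-transcript arrays. APPPS1 mice carry transgenes driven by a *Thy1* promoter, mutant human APP among them, and form amyloid plaques in the brain; FVB is an inbred strain. The 3 control arrays came from APPPS1-FVB mice and the 3 knockout arrays from such mice crossed to an *Abcc1* knockout. *Abcc1* encodes an ATP-binding cassette transporter that exports glutathione conjugates and cysteinyl leukotrienes. Array medians of the tested probe sets were 7.04, 7.05 and 7.06 on the log2 scale in control 1, control 2 and control 3, and 7.07, 7.09 and 7.05 in knockout 1, knockout 2 and knockout 3. *Abcc1* and *App* were not analysed here, and nearly all genes analysed lie on chromosomes 1, 10, 11, 12 and 13.

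The comparison asked which brain transcripts differ when *Abcc1* is lost on the amyloid background. Of 58919 probe sets, 3 rose and 0 fell in the knockout at a limma adjusted p below 0.05, and none of the 3 carries a gene symbol. The largest rise was at probe set 10360276, from 5.23 ± 0.16 (SD, n = 3) in the controls to 10.26 ± 0.38 (SD, n = 3) in the knockouts. This was a log2 difference of 5.03 (SE 0.20) or 32.7-fold, with an adjusted p of 0.0112. Probe set 10360289 rose 15.1-fold (log2 difference 3.91, SE 0.21, adjusted p = 0.0363) and probe set 10360348 rose 14.9-fold (log2 difference 3.90, SE 0.24, adjusted p = 0.0452). By the order of IDs, 10360276 and 10360289 lie between *Atp1a4*, a sodium pump subunit, and *Kcnj9*, a potassium channel subunit, and 10360348 lies between *Ackr1*, a chemokine-binding receptor, and *Cadm3*, a neural cell adhesion molecule, all on chromosome 1. The 10 probe sets adjacent to each had median log2 differences of 0.048, 0.075 and 0.13. Single probe sets nearby rose too, short of the threshold. Probe set 10360279, also between *Atp1a4* and *Kcnj9*, had a log2 difference of 1.05, and 10360353 of *Cadm3* had 1.60. The count was 0 without control 1, without control 2, without control 3, without knockout 1 and without knockout 3, and 4 without knockout 2. It was 4 up and 2 down after quantile normalization and 5 up and 2 down after median centring, where the 2 down, 10375053 and 10375060, hold identical values on all arrays and are 1 measurement.

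With a variance trend and robust moderation 21 probe sets passed, the 3 above among them, 15 up and 6 down. Those with a gene name, chosen after their values were seen, were all higher in the knockout at those probe sets. *Cert1*, the ceramide transfer protein, had a log2 difference of 2.87, *Lama2*, a laminin chain, 3.39, *Cdc42bpa*, a cytoskeletal kinase, 2.70, *Fmn2*, an actin nucleator, 1.83, *Cadm3* 1.60, *Rgs7*, a regulator of G protein signalling, 1.34, and *Plpp1*, a lipid phosphatase, 1.15. The other 17 probe sets of *Cert1* had a median of -0.05 and its brightest was at -0.17, and the other 9 of *Plpp1* had a median of -0.23. *Catspere2* had 1.99 at the probe set that passed, but another of its probe sets was at -1.70, the other 11 had a median of -0.80 and its mean over all probe sets was -0.53. For *Ncstn*, which encodes the gamma-secretase subunit nicastrin, 2 of 17 probe sets passed, with log2 differences of 1.10 and 1.99. Means over all probe sets were smaller for each of these genes, at 0.17 for *Ncstn*, 0.27 for *Cert1*, 0.10 for *Lama2*, 0.29 for *Cdc42bpa*, 0.54 for *Fmn2*, 0.15 for *Cadm3*, 0.22 for *Rgs7* and -0.09 for *Plpp1*. The 6 lower ones, 10375052 to 10375054 and 10375059 to 10375061, each carry several symbols and are left unnamed, and by the order of IDs they lie between the globin genes *Hba-x*, *Hbq1b* and *Hbq1a* on chromosome 11. *Slc4a1*, the anion exchanger of red cells, had a log2 difference of -0.36 (SE 0.07, limma adjusted p = 0.215) over the mean of its probe sets and 0.24 (SE 0.25) at its brightest. The log2 differences of the 6 ran from -1.25 to -0.75, their knockout values lay below all control values, and their adjusted p without the trend was between 0.0519 and 0.123.

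At a raw p below 0.05 there were 4531 probe sets, 2799 higher and 1732 lower in the knockout, where 2946 would be reached if no probe set differed. The higher ones made up 61.8% as deposited, 52.0% after quantile normalization and 51.2% after median centring. Tested per gene with limma, 0 of 5017 genes passed either by the mean of all probe sets (399 higher and 307 lower at raw p below 0.05, smallest adjusted p 0.215) or by the brightest probe set (186 higher and 296 lower at raw p below 0.05, smallest adjusted p 0.262). The 3 knockout values lay beyond all 3 control values in 731 genes, or 14.6%, where chance gives 10%.

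No named gene passed the threshold, so the following are values and not calls. Of the genes with the smallest raw p on the higher side, *Itpkb*, a kinase of inositol trisphosphate, had 8.60 ± 0.11 (SD, n = 3) in controls and 9.51 ± 0.23 (SD, n = 3) in knockouts, a log2 difference of 0.91 (SE 0.14). *Serpina9*, a serine protease inhibitor, differed by 0.69 (SE 0.11) and *Fam177a* by 0.55 (SE 0.11). *Ackr1* differed by 0.51, *Nvl*, an ATPase of ribosome assembly, by 0.44, *Myo19*, a mitochondrial myosin, by 0.43, *Exoc3l4* by 0.40 and *Shisa6*, a partner of AMPA receptors, by 0.39. The mean over all probe sets of *Exoc3l4* gave a log2 difference of -0.02, against the sign of its brightest probe set, and that of *Itpkb* gave 0.27. On the lower side, the organic anion transporter gene *Slco6b1* had a log2 difference of -0.74 (SE 0.13), *Col13a1*, a transmembrane collagen, -0.52, *Havcr1* -0.46, *Gpx3*, the secreted glutathione peroxidase, -0.41, *2700097O09Rik* -0.41, *Tfcp2l1*, a transcription factor, -0.39, and *Slc16a9*, of the monocarboxylate transporter family, -0.36. *E430029J22Rik* had -0.66 at a dim signal of 3.15 ± 0.06 (SD, n = 3) in controls. *Slco6b1* was dim too, at 4.78 ± 0.10 (SD, n = 3) in controls and 4.04 ± 0.20 (SD, n = 3) in knockouts. The array's control features had a median of 4.25 in knockouts. Over the mean of all probe sets, the log2 difference was -0.05 for *Slco6b1* and -0.06 for *Col13a1*. Adjusted p of these 16 genes lay between 0.353 and 0.554.

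**Figure D1:**
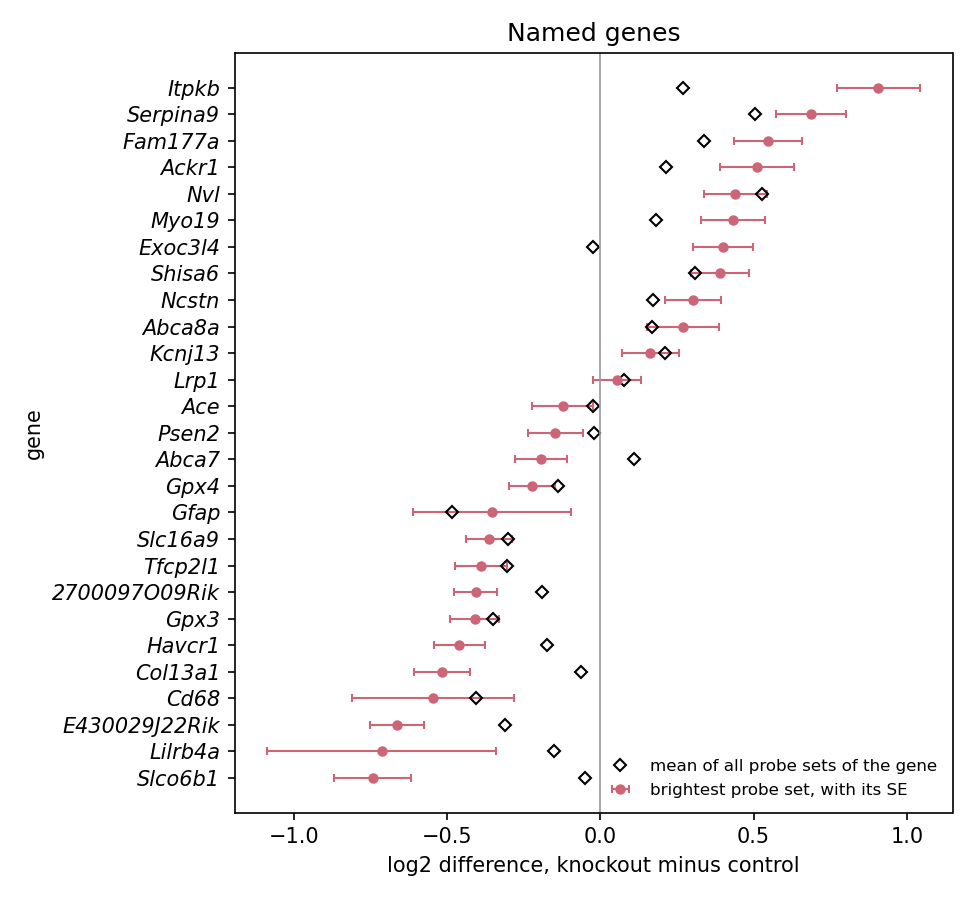
Log2 difference, knockout minus control, of the 27 named genes (vertical axis). Filled points are the brightest probe set with bars of 1 SE, and open diamonds are the mean over all probe sets of the gene, 3 arrays per group; *Itpkb* is the highest at 0.91 and *Slco6b1* the lowest at -0.74, and *Exoc3l4* and *Abca7* have the 2 measures on opposite sides of 0.

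Neither amyloid production nor amyloid clearance genes passed as lists. Only 6 of the 21 genes fixed for amyloid processing and 2 of the 25 for amyloid clearance were measured, so most of each list was not tested. Of 6 measured amyloid processing genes, 3 were higher and 3 lower as deposited, 4 were lower after either normalization, and 0 passed (camera adjusted p of the list = 0.750). Among the 6, *Aph1a* is placed on chromosome 3, but its brightest probe set has an ID among those of chromosome 1 genes. *Ncstn* had a log2 difference of 0.30 (SE 0.09) at its brightest probe set, and *Psen2* -0.15 (SE 0.09), with 0.17 and -0.02 over the means of their probe sets. The mean for *Ncstn* is raised by the 2 of its 17 probe sets at 1.10 and 1.99, so it does not show a rise across the gene. The 10 probe sets adjacent to the one at 1.10 had a median of 0.07. Of the amyloid clearance list only *Abca7* and *Lrp1* were measured. *Lrp1*, a lipoprotein receptor that takes up amyloid peptide, differed by 0.05 (SE 0.08), and *Abca7*, a lipid transporter tied to Alzheimer risk, by -0.19 (SE 0.08), with 0.11 over the mean of its probe sets (camera adjusted p of the list = 0.754). Of 9 measured ABC transporter genes, 7 were lower and 2 higher and 0 passed, with a median of -0.07 (camera adjusted p = 0.750). Over the mean of all probe sets of these genes, 4 of 9 were lower and the median was 0.02. *Abca8a* had the smallest raw p among them, with a log2 difference of 0.27 (SE 0.12). In the choroid plexus list, 2 of 5 genes were lower and 3 higher (camera adjusted p = 0.754), with *Kcnj13*, a potassium channel gene, at 0.16 (SE 0.09) and *Ace*, the angiotensin-converting enzyme, at -0.12 (SE 0.10), with -0.03 over the mean of its probe sets.

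Most measured microglial and astrocytic response genes had lower values in the knockout, and neither list passed. Values leaned slightly lower over all 5017 genes too, with a median log2 difference of -0.02 at the brightest probe set. Of 10 measured genes of plaque-associated microglia, 7 were lower and 3 higher, and 8 were lower after either normalization, with a median log2 difference of -0.16 as deposited (camera adjusted p = 0.538). *Cd68*, a lysosomal protein of phagocytes, was at 8.91 ± 0.17 (SD, n = 3) in controls and 8.36 ± 0.52 (SD, n = 3) in knockouts, and the receptor gene *Lilrb4a* had a log2 difference of -0.71 with an SE of 0.37, but -0.15 (SE 0.17) over the mean of its probe sets. All 6 measured genes of reactive astrocytes were lower by their brightest probe sets, with a median of -0.10 (camera adjusted p = 0.538), and 4 of 6 by the mean of all probe sets, with a median of -0.02. Among them *Gfap*, the intermediate filament of astrocytes, was at 11.40 ± 0.31 (SD, n = 3) in controls and 11.05 ± 0.44 (SD, n = 3) in knockouts, a log2 difference of -0.35 (SE 0.26). The limma adjusted p of *Cd68*, *Lilrb4a* and *Gfap* was 0.674, 0.686 and 0.761. Without knockout 2, their log2 differences were -0.25, -0.37 and -0.10, and that of *Gfap* was -0.18 without control 3.

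Genes of glutathione metabolism and oxidative stress were lower in 7 of 9 measured members, with a median log2 difference of -0.16. The list had the smallest p of the 42, with a camera raw p of 0.00147 and an adjusted p of 0.0617, above the threshold. *Gpx3* was at 9.19 ± 0.08 (SD, n = 3) in controls and 8.78 ± 0.03 (SD, n = 3) in knockouts, and it passed when adjusted over the list alone (limma adjusted p = 0.0183). *Gpx4*, the peroxidase of lipid peroxides, had a log2 difference of -0.22 (SE 0.08), *Prdx6*, a peroxiredoxin, -0.22 (SE 0.09), *Gstt1*, a glutathione transferase, -0.17 (SE 0.10) and *Mgst3*, a microsomal glutathione transferase, -0.16 (SE 0.08). *Txnrd1*, the thioredoxin reductase gene, was at -0.01, and *Ggt1* and *Ggt5*, which break down extracellular glutathione, both at 0.02. After quantile normalization 8 of 9 were lower. After median centring the same 7 were lower as before, and *Ggt1* and *Ggt5* showed no difference beyond rounding. The adjusted p was 0.862 with an estimated correlation and 0.226 with fry. Over the means of all probe sets it was 0.0121, and 0.704 with an estimated correlation. Of 20 alternatives, 7 put the list past the threshold, with adjusted p from 0.0121 to 0.862.

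**Figure D2:**
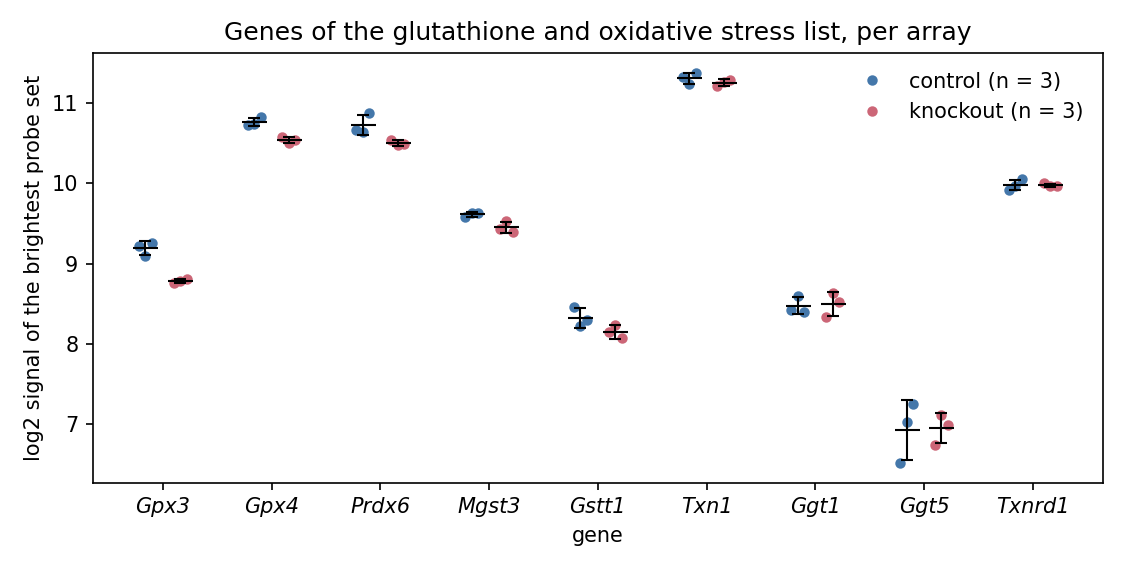
Log2 signal (vertical axis) of the brightest probe set of the 9 measured genes of the glutathione and oxidative stress list, per array. Points are arrays, 3 per group, and the black marks are the group mean with 1 SD; the groups do not overlap for *Gpx3*, *Gpx4*, *Prdx6* and *Mgst3*.

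Over all 42 lists with limma, 0 passed with camera (3 at raw p below 0.05), 0 with an estimated correlation (0 at raw p below 0.05) and 0 with fry (5 at raw p below 0.05). All 5 measured synapse genes were higher as deposited, with a median log2 difference of 0.07 (camera adjusted p = 0.191), 4 of 5 were higher after either normalization, and 3 of 5 by the mean of all probe sets, with a median of 0.03. *Homer1*, a scaffold of the postsynaptic density, had the largest value, 0.19 (SE 0.07), and *Dlg4*, another such scaffold, 0.11 (SE 0.07). With a variance trend in camera, the synapse list (adjusted p = 0.0299) and the glutathione list (adjusted p = 0.0280) both passed, and both had an adjusted p of 0.862 with an estimated correlation. The 3 measured genes of glucocorticoid response were lower (camera adjusted p = 0.538), with the kinase gene *Sgk1* at -0.28 (SE 0.13), *Nfkbia* at -0.23 and the clock gene *Per1* at -0.11. Over all lists, 0 members passed over all probe sets. By brightest probe sets 2 passed adjusted over the list alone, *Gpx3* and *Vip*, the neuropeptide gene that was the 1 measured member of its list (log2 difference -0.33, SE 0.13). By the mean of all probe sets 11 did, in 10 lists, and *Vip* did not (-0.22, SE 0.11). *Homer1* is counted in both the synapse and the immediate early list.

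A scan of the 5 chromosomes for windows with many large differences, at probe sets with 1 symbol, picked out 2 runs of neighbouring genes. On chromosome 1, a run of 85 neighbouring genes held 12 of them among 754 probe sets (1.59%), in genes from *Cadm3* to *Nvl*, and on chromosome 13 a run of 60 genes held 8 among 559 (1.43%), in genes from *Cert1* to *Dhx29*. Elsewhere on the 5 chromosomes there were 55 among 52063 (0.106%), a contrast that picking the runs by their counts in part builds in. Of 10000 random gene orders, 2 reached the highest window of chromosome 1. That of chromosome 13 was reached by 303, which leaves chance open there. A large difference was a log2 difference of at least 1 in size with a raw p below 0.01. Of the 20 in both runs 18 were higher in the knockout, with a median log2 difference of 1.59, while the 259 other probe sets of the same 12 genes had a median of 0.14, and from -0.80 (*Catspere2*) to 0.45 (*Nvl*) by gene. The gap between the 20 and the 259 is in part built in by the cut on size. *Itpkb*, *Nvl*, *Ackr1* and *Psen2* lie in the run on chromosome 1, and by the order of IDs so does the called probe set 10360348.

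**Figure D3:**
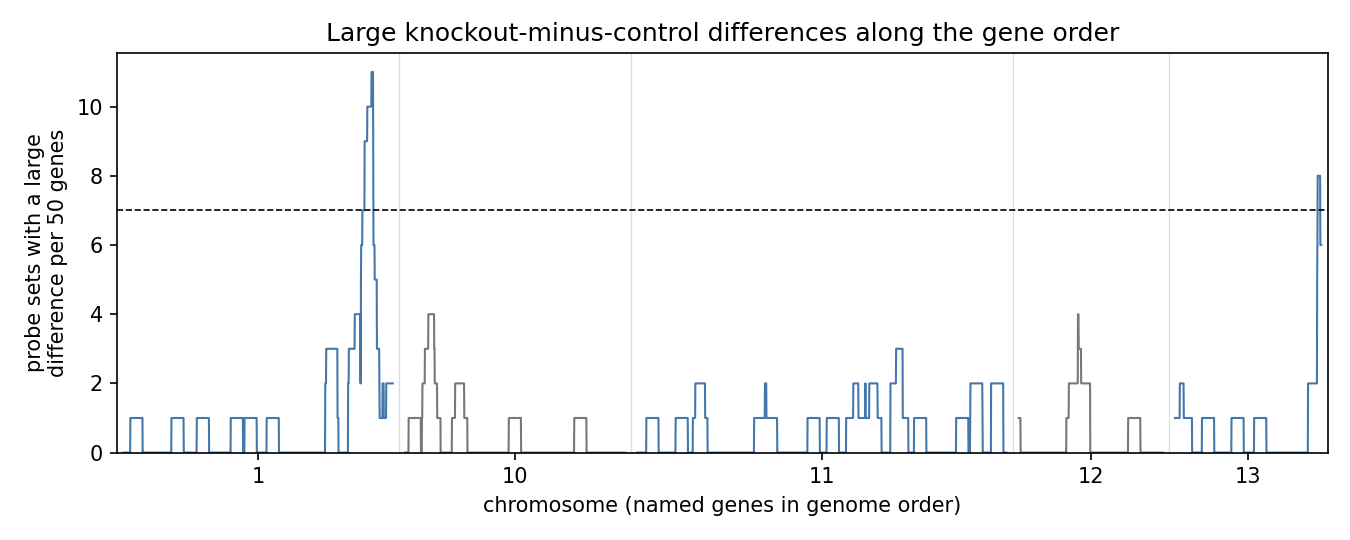
Number of probe sets with a large difference (vertical axis) in windows of 50 neighbouring genes, along the 4918 genes in genome order on chromosomes 1, 10, 11, 12 and 13 (horizontal axis). The dashed line at 7 is the 95th percentile of the highest window over 10000 random gene orders; chromosome 1 reaches 11 and chromosome 13 reaches 8, and the other chromosomes stay at 4 or below.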

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

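The control features of the array, which were left out of the tests above, were brighter in the knockout arrays. Their median log2 signal was 4.12 ± 0.036 (SD, n = 3) in controls and 4.25 ± 0.047 (SD, n = 3) in knockouts, a difference of 0.133, and all 3 knockout arrays lay above all 3 controls. The exact two-sided permutation p was 0.1, the smallest that 3 against 3 can give. Tested with limma within the 6616 control features, 0 passed the threshold and 721 had a raw p below 0.05, of which 607 were higher in the knockout. Feature by feature, the median log2 difference of the control features was smaller, at 0.057. Tested probe sets of low signal did not share the shift by this measure. The dimmest of 5 groups of equal size by mean signal, with a median signal of 3.61, had a median log2 difference of -0.01, and the brightest 0.03. No explanation was tested.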

How the results depend on the processing

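The alternatives with gene means or brightest probe sets per gene, control features, lists of at least 3 members, gene means with fry or an estimated correlation, the runs left out and the span trend were chosen after seeing the data. The count of probe sets past the threshold, 3, became 6 with quantile normalization, 7 with median centring, 7 with array weights, 7 at adjusted p below 0.1, 19 without the dimmest 1 in 3 probe sets and 21 with trend and robust moderation, and each of these called the 3. It was 0 with brightest probe sets and 0 with gene means tested per gene, fits that the 3 could not enter because they carry no symbol. It was 3 with control features included and 0 to 4 without 1 array. Without the genes of the 2 runs it was also 3, but that fit keeps probe sets without a symbol. Among these is 10360348, which by the order of IDs lies in the run on chromosome 1. The cause was not tested. Leaving out dim probe sets lowered the number tested from 58919 to 39280. That alone is too little for the fall of the smallest limma adjusted p from 0.0112 to 0.00132.

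The count of lists past the threshold, 0, became 1 with quantile normalization, 2 with trend and robust moderation (camera's variance trend), 1 with the mean of all probe sets, 1 with that mean and fry, 1 with lists of at least 3 members, and 0 to 1 without 1 array (1 without control 1 and 1 without knockout 2). The glutathione list passed in each of these, at medians of -0.193, -0.16, -0.114, -0.114 and -0.16, and of -0.177 without control 1 and -0.198 without knockout 2. With an estimated correlation 0 lists passed, and the adjusted p of this list was 0.862 with brightest probe sets and 0.704 with gene means. Without 1 array its median was -0.198 to -0.132, and it did not pass without the other 4. Its median was below 0 in each setting that changes the values behind it (both normalizations, array weights, gene means, the span trend removed and each array left out). The cause was not tested.

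With the replicate block, 0 probe sets and 0 lists passed. The numbers gave no sign of pairing: deviations from the group means correlated at 0.04, -0.07 and -0.10 between same-numbered arrays, and control 1 correlated best with knockout 3 (0.05).

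The 27 named genes stayed short of the threshold in all 321 values over 12 settings and kept their direction at the brightest probe set, which the dim filter, the variance model and the block cannot change; by the mean of all probe sets *Exoc3l4* (-0.02) and *Abca7* (0.11) turned. Besides the microglial and astrocytic genes above, leaving out 1 array moved the value of *Ace* to -0.06 (without control 2) and -0.07 (without knockout 2), *Psen2* to -0.10 and *Lrp1* to 0.01 (both without knockout 1). The count at raw p below 0.05 was 3717 to 5279 where all or the brighter probe sets were tested. Alternatives for *Abcc1* and its neighbours could not be run because those genes were not analysed here, nor those for pseudocounts, since values were on the log2 scale. The number of arrays limits what could pass.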

Other observations

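Among lists not described above, all 6 measured ribosomal protein genes were lower in the knockout, with a median log2 difference of -0.10 (camera adjusted p = 0.538) and *Rpl23* at -0.23 (SE 0.09). However, *Rpl27*, *Rplp0* and *Rps23*, each with 1 probe set, were at -0.02, -0.02 and -0.03, near the median of -0.02 over all genes. *Rplp0* is placed on chromosome 5, but its probe set has an ID among those of chromosome 13 genes. Lysosome and autophagy genes were lower in 6 of 7, and in 7 of 7 after either normalization, with a median of -0.13 as deposited (camera adjusted p = 0.538); *Npc2*, a cholesterol carrier of lysosomes, was at -0.18 (SE 0.11). Of 8 meningeal and fibroblast genes 7 were lower, and 8 after either normalization, with a median of -0.05 as deposited (camera adjusted p = 0.718). Leukotriene genes went both ways, 2 lower and 3 higher of 5 as deposited and 3 lower and 2 higher after either normalization, and 1 lower by the mean of all probe sets (camera adjusted p = 0.750), with the lipoxygenase gene *Alox15* at 0.31 (SE 0.15) and *Lta4h* at -0.14 (SE 0.09). Over the mean of all probe sets, *Alox15* was at 0.08 and *Lta4h* at 0.01. The highest value of the table belonged to a probe set of *Copa*, 14.41 in knockout 1 against 11.63 to 11.81 on the other arrays.

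The tests of the runs (random gene orders and the other probe sets of the genes), the splits for the counts of probe sets and lists, the mean without *Gpx3* and removal of the span trend were chosen after the results were seen; the matched lists and the other splits were prompted by the patterns and set out before their own values were computed. Splitting the 6 arrays into 3 and 3 in all 10 ways is too few for a share under 0.05. The real split put 0 lists past the threshold and the highest other 1, so all 10 splits gave as many. In the other cases 1 of the 10 splits, the real one, gave a result as large. The real split called 3 probe sets and the highest other 0, with 4531 against 3512 at raw p below 0.05. Its highest window of large differences was 11 against 6, and the camera p of the glutathione list was 0.00147 against a smallest other of 0.00591.

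The first pattern is the grouping of large differences on chromosomes 1 and 13. Random placement is argued against for chromosome 1, since 2 of 10000 random gene orders gave a window of 11 or more, but 303 gave the 8 of chromosome 13, which leaves chance open there. For a change in the level of whole genes, the other 259 probe sets of the same genes were compared with the 20. They had a median log2 difference of 0.137 against 1.59. The 20 were chosen by their size in these same data, so part of this gap is built in. Over all 279 probe sets of these genes, chosen or not, the median was 0.15. This argues against a change of the whole genes as large as in the 20, but not against a smaller one. By gene that argument is weaker. The ratio of the others' median to the moved probe set was 0.47 for 1 probe set of *Catspere2* and 0.31 for *Nvl*. For the 3 of *Fmn2*, set against the same others, it was 0.30, 0.18 and 0.17. A change of the whole gene stays open for these genes. The ratio was -0.40 for the other of *Catspere2*, whose neighbours went the opposite way. It was below 0.25 in size for 16 of the 20, the lower ones of *Fmn2* among them. Sequence variants under single probe sets, carried in segments of another strain's chromosome, may be a candidate explanation for those of the 16 outside *Fmn2*. The ratios cannot show it, because the choice of the 20 in part sets them. Altered exon use would look alike, and neither strain origin nor exon use was tested. The 3 called probe sets carry no symbol and were not part of these tests. By the order of IDs, however, 10360348 lies in the run on chromosome 1. Of the 21 probe sets called with trend and robust moderation, 8 lie in the 2 runs. Others of the 21 lie outside the runs but precede 10360348 on chromosome 1 by the order of IDs, and all of these rose. They are 10360276, 10360279 and 10360289 between *Atp1a4* and *Kcnj9*, 10360207 and 10360210 of *Ncstn*, and 10360089. Whether they belong to the same pattern as the run was not tested.

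The second pattern is the lower glutathione list, where *Gpx3*, *Gpx4*, *Prdx6* and *Mgst3* had groups that did not overlap. Gene span is argued against as the cause, because the list's median lay at percentile 0.06 of 10000 random lists matched on span and signal. Without *Gpx3* the list's mean was still -0.1, at percentile 1.33 of matched lists, so the lower values did not rest on that gene alone. Neither percentile allows for the choice of this list as the smallest p of 42, or for correlation between its genes. These percentiles therefore do not weigh against chance. With the span trend removed the median was -0.13 and the camera adjusted p 0.0740, against -0.16 and 0.0617 before, where the alternatives ranged from 0.0121 to 0.862. The knockout itself, chance and unrecorded differences between the samples all stay open, and no test here decides between them.

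The third pattern is a trend with gene span: across genes, which are not independent replicates, the mean log2 difference of a gene correlated with its span at a rank correlation of 0.227, and the brightest probe set at 0.113. The medians of 5 groups of equal size, from the shortest to the longest genes, were -0.03, -0.03, -0.01, 0.01 and 0.04. The highest other split of the arrays gave 0.197, and 1 of 10 splits reached the real value, so the data leave open whether the trend belongs to the knockout. A difference in RNA quality could give such a trend, and no measure of it was at hand to test; no biological explanation was tested.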
